A study of Homo sapiens with 4 samples.

How the data were processed

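Chromatin came from tumours of MCF10DCIS cells with an inducible hairpin against DNp63, grown in the mammary fat pads of nude mice on a control or a doxycycline diet. Per the labels' protocols, material was fixed with 1% formaldehyde, sheared to 300 to 500 bp and precipitated with 4 µg of antibody against DNp63 or Pol2, and input DNA was also made into libraries. The 4 libraries form 4 groups of 1, named by tumour and antibody from the sample labels. How many tumours went into a library was not given in the sources used here. Per the submitters' processing notes, reads were aligned with BWA to hg38; its version was not given. The peak names in the files show that MACS2 called the peaks, 1 list per library, so no list pools samples. The MACS2 version, its cutoff, any filter on reads or on repeated regions, the handling of mouse reads, the read depth and which input was used were not given in the sources used here.

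Each deposited list gives peak positions, and per the file headers the pileup signal at the summit (fragments, whole numbers), the −log10 p-value and q-value, and the fold enrichment. The lowest −log10 p-value was 7.09 in both DNp63 lists and 7.01 in both Pol2 lists, so each deposited list ends near the same p-value. The authors' fold enrichment is the ratio of summit pileup plus 1 to local background plus 1 within a library, a relation checked on the values. It is a property of a peak, and it was used to describe, rank or filter peaks within a list. Inverting it gave each peak's local background, whose lowest value (1.10, 1.04, 1.43 and 1.42 for control DNp63, knockdown DNp63, control Pol2 and knockdown Pol2) is the caller's lowest level. The knockdown to control ratio of this level was 0.950 for DNp63 and 0.995 for Pol2, equal to the ratio of the shortest peak lengths (192 against 202 bp and 201 against 202 bp). Within an antibody the level thus followed the shortest length and showed no further difference between tumours. That length alone does not set it, since both control lists had 202 bp but levels of 1.10 (DNp63) and 1.43 (Pol2). How the caller scaled the reads was not given, so no read depth is taken from the level. Positions were used as deposited, counted from 1, and 0 peaks lay outside the autosomes and X.

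Everything else was computed here with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Peaks of both tumours were shared where they overlapped by at least 1 bp. Genes were the 19974 protein-coding genes on these chromosomes in a RefSeq gene table of GRCh38.p14, the same coordinates as hg38. The table gives gene starts and ends without strand, transcripts or exons, so both gene ends were used in place of the 5' end, and no peak is called exonic, intronic or at a promoter. A gene had DNp63 when a peak midpoint lay in it or within 10000 bp of it, and Pol2 when a peak overlapped 1000 bp on either side of either end. A peak in several genes was named by the gene with the nearest end. Neighbouring or overlapping genes can share a peak. Random placement kept each DNp63 peak's chromosome and length (100 draws).

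Before the data were examined, 22 gene lists were fixed: basal keratins and markers, myoepithelial contractile, hemidesmosome and basement membrane, luminal, NOTCH, WNT, hedgehog, TGF-beta and BMP, mesenchymal transition and invasion, chemokines and cytokines, interferon response, antigen presentation, p53 targets, cell cycle, immediate early and AP-1, hypoxia and glycolysis, cornified envelope and differentiation, housekeeping, markers of fibroblast, immune and endothelial cells, and genes of unrelated tissues. Of their 389 entries 388 matched the table. Each list's count was set against 10000 random lists matched on 10 bins of gene length, and its mid-rank percentile among them is a description of these libraries, not a p-value. Genes are not replicates, and 22 lists were examined per antibody, so a few extreme percentiles arise by chance. Also fixed beforehand was which genes are named: TP63, for each antibody the genes of the 8 control-only, 8 knockdown-only and 6 shared peaks with the highest fold enrichment among peaks assigned to a protein-coding gene by these rules, and up to 4 members of each list with the strongest peak. Members found in 1 tumour are named as well. Not every gene that this rule picks is named in the text. For list members, the value given for each tumour is that of the member's strongest peak and of the strongest peak overlapping it in the other list.

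Shares carry exact Clopper-Pearson 95% intervals (scipy binomtest), and ratios of peak numbers carry the same exact interval of the knockdown share of both counts, turned into a ratio. Both cover counting error only. With 1 library per group there is no spread between replicates, and a difference between lists compares these libraries, not the diets. Alternatives covered the overlap rule, stricter peak sets, lists of equal length, other gene rules and removal of chromosome 7. The planned search for p63 response elements and the alternative that uses the 5' end of any transcript were not run, since no genome sequence or transcript positions were used here. The overlap, gene and random-list steps were tested on simulated data: all 3979 simulated peaks and 8703 genes were answered as by brute force, 100% of planted overlaps were recovered, and 6% of 200 random lists passed percentile 95 against 100% of 200 planted ones.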

Results

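Chromatin occupancy was profiled in tumours of MCF10DCIS, a human basal-like breast cancer cell line that forms comedo ductal carcinoma in situ like lesions when grafted into mice. The cells carried a doxycycline-inducible short hairpin RNA against DNp63, the p63 isoform that lacks the N-terminal transactivation domain and marks basal and myoepithelial cells. They were injected into the mammary fat pads of nude mice, and the hosts were fed a control diet (control tumour) or a doxycycline diet that switches on the hairpin (knockdown tumour). Each of these names stands for all material of a condition, since the number of tumours was not given. Chromatin immunoprecipitation and sequencing were done for DNp63 and for RNA polymerase II (Pol2), giving 4 peak lists with 1 library per antibody and tumour. No spread between replicates can be given, so no test between tumours was made, and each interval is an exact Clopper-Pearson 95% interval that covers counting error only. The lists held 23266 DNp63 peaks in the control and 22239 in the knockdown tumour, and 30917 Pol2 peaks in the control and 27242 in the knockdown tumour. DNp63 peaks covered 12.5 Mb in the control and 10.99 Mb in the knockdown tumour, and Pol2 peaks covered 24.4 Mb and 19.0 Mb. The read depth was unknown. All fold enrichments are the authors' values for single peaks against the background of their own library. Where the values of both tumours stand side by side they are descriptions of each list, and no change is read from them.

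The targeted gene was examined first. TP63, the gene that encodes all p63 isoforms, lies on chromosome 3 from 189596746 to 189897276 (hg38). The control list held 8 DNp63 peaks in or within 10 kb of it, and the knockdown list held 6. Both strong sites inside the gene were present in both tumours. The peak at 189824351 to 189826387 had a fold enrichment of 95.3 in the control list, and the overlapping knockdown peak reached 74.3. The peak at 189832548 to 189835642 had 94.8, and the stronger of the knockdown peaks overlapping it had 84.3. All other DNp63 peaks at the locus had a fold enrichment below 10 in either list. Pol2 was found at 4 positions inside TP63 in the control and 2 in the knockdown tumour, and within 1 kb of neither annotated end in either. The strongest of these, at 189789507 to 189789864, had 12.3 in the control, and the knockdown peak overlapping it had 9.90. A hairpin acts on the transcript, and peak lists do not measure the amount of protein, so these values do not check the knockdown.

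**Figure D1:**
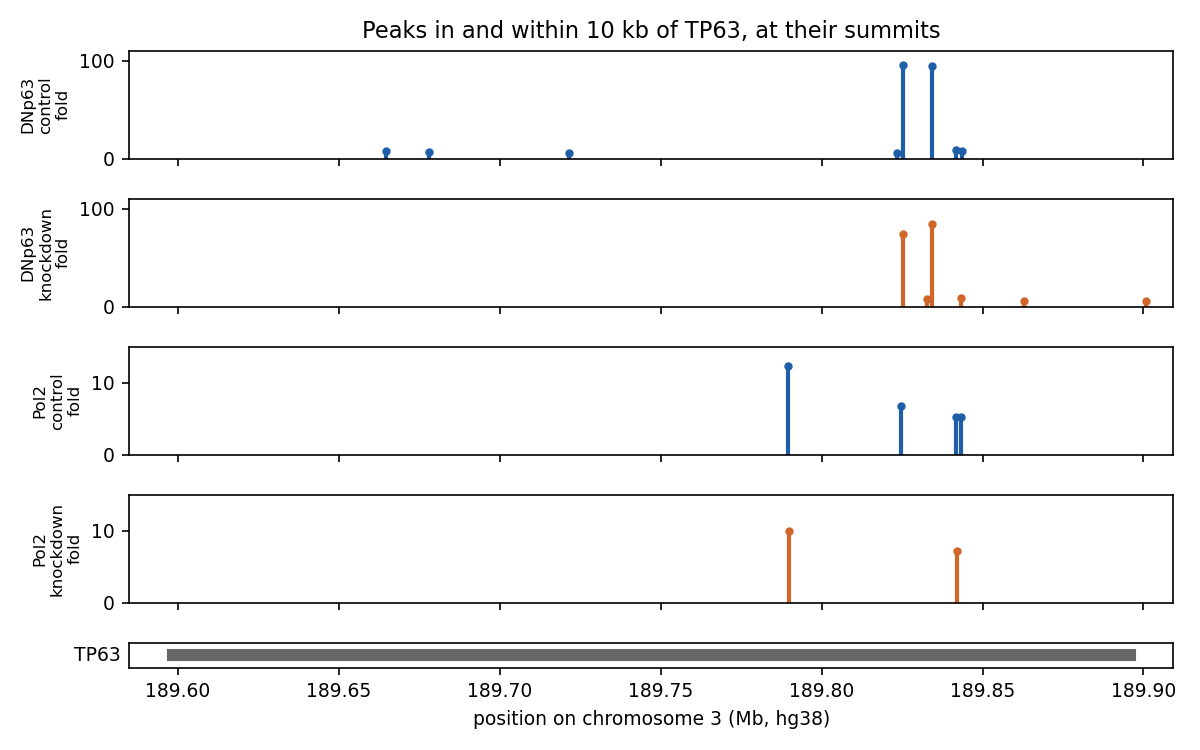
Peaks in and within 10 kb of TP63 in the 4 lists, drawn at their summits; the horizontal axis is the position on chromosome 3 in Mb (hg38), the vertical axis the authors' fold enrichment (note the smaller scale for Pol2), and the grey bar the annotated gene. The pair of strong DNp63 peaks inside the gene stands out in both tumours, with 95.3 and 94.8 in the control and 74.3 and 84.3 in the knockdown list.

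The first comparison asks which DNp63 sites were found with and without the hairpin. Most sites were common to both tumours. Of the control peaks, 17651 overlapped a knockdown peak (75.9%, 95% interval 75.3 to 76.4), and of the knockdown peaks 17869 overlapped a control peak (80.3%, 79.8 to 80.9). The shared sites with the highest fold enrichment among those assigned to protein-coding genes were inside MINK1, a kinase of the JNK pathway (fold enrichment 138.8 control, 127.6 knockdown), and KIAA1217 (116.0 and 104.9). Others lay at the end of DHRS3, a retinaldehyde reductase (138.8 and 136.1), at AXL, a receptor tyrosine kinase (116.5 and 98.7), in GADD45A, a DNA damage response gene (112.8 and 105.2), and in CHD9NB (111.1 and 112.1). Among the 10% of control peaks with the highest fold enrichment, all 2327 were shared (lower limit 99.8%), and among the lowest 10% 1024 of 2327 were (44.0%, 42.0 to 46.1). The knockdown list ran from 48.7% (46.6 to 50.8) in its lowest 10% to all of 2224 in its highest. The 5615 control-only peaks had a median fold enrichment of 7.26, against 13.4 for the shared control peaks. For the 4370 knockdown-only peaks these medians were 7.34 and 13.7.

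**Figure D2:**
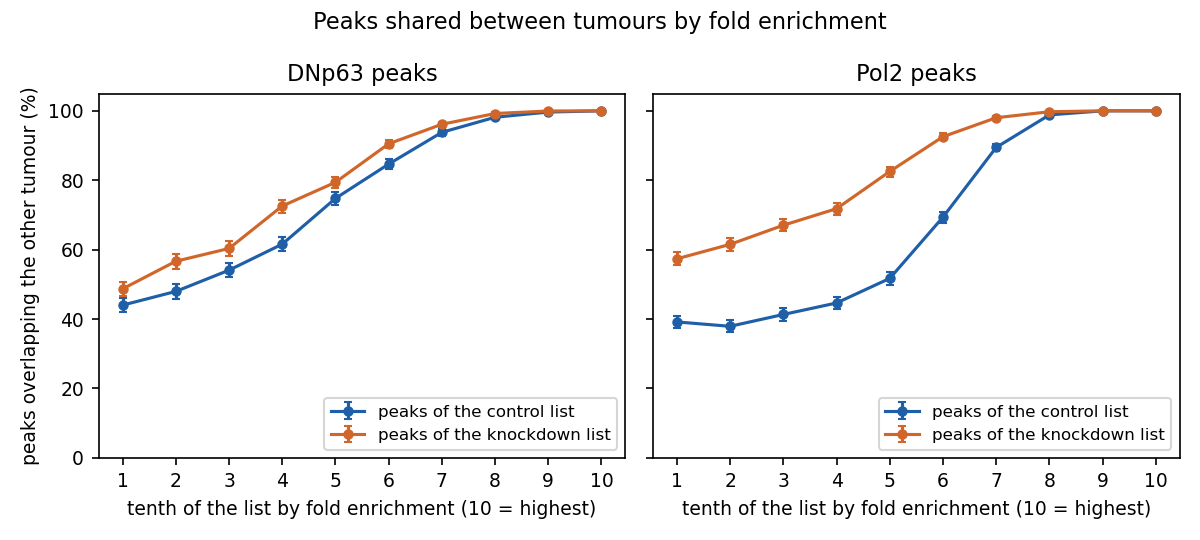
Share of peaks (%) that overlap a peak of the other tumour by at least 1 bp, for each 10% of a list ordered by fold enrichment; points are single lists (1 library each) and bars exact 95% intervals. Sharing rises from 44.0% and 48.7% in the lowest 10% of the DNp63 lists to 100% in the highest, and from 39.2% and 57.4% for Pol2.

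Among control-only DNp63 peaks assigned to protein-coding genes, those with the highest fold enrichment were in ERN1, a sensor of endoplasmic reticulum stress (21.4, chromosome 17, 64106391 to 64106989), CRYL1 (21.4), CADPS (21.0), PDZRN3 (20.9) and ITGB1, the beta-1 integrin (20.03, chromosome 10, 32909054 to 32909596). NRXN3 (19.4) and AFF2 (18.3) followed. Of the 8 genes so chosen, 3 (CADPS, PDZRN3 and AFF2) had no other DNp63 peak in the knockdown list. The corresponding knockdown-only peaks were in LCMT1 (23.3, chromosome 16, 25152939 to 25153260), TNK2, a tyrosine kinase (22.7), DENND5B (20.9), SMUG1, a uracil-DNA glycosylase (20.9), NRG3 (20.8) and PHTF2 (19.1), and beside AGMAT (21.0) and SOS1, a RAS exchange factor (19.98). PHTF2 lies on chromosome 7, which is described last. LCMT1 and SMUG1 had no DNp63 peak in the control list. The highest of all peaks in 1 list alone, 32.9 in the control and 27.4 in the knockdown list, were assigned to no protein-coding gene. Under the rule that a peak's midpoint lies in a gene or within 10 kb of it, 8069 of 19974 protein-coding genes had DNp63 in both tumours, 968 in the control only and 1073 in the knockdown only. The gene counts depended on the rule and on the peaks used, with 4301 genes in both when a peak had to lie within 5 kb of a gene end, and 5235, 605 and 652 genes in both, the control only and the knockdown only with the stronger 50% of each list.

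Gene lists fixed beforehand were examined for DNp63, each set against 10000 random lists of genes of like length. Each percentile and random mean refers to all members with a peak in the control, unless control-only or knockdown-only genes are named. Basal epithelial genes carried DNp63 almost throughout. Of 18 basal keratins and markers, 15 had DNp63 in both tumours (percentile 100 in the control, random mean 7.54). Strong sites besides those of TP63 were at CDH3, which encodes P-cadherin (71.7 control, 70.7 knockdown), and KRT16 (53.9 and 57.2). KRT15 (5.80) and KRT6A (5.33) had a peak in the control only, and KRT14 in the knockdown only (12.0). Hemidesmosome and basement membrane genes were bound in both tumours in 18 of 20 cases (percentile 99.9 in the control), including LAMB1 (44.3 and 64.1), PLEC (55.8 and 62.9) and COL7A1 (49.9 and 46.7). COL4A1 had a peak in the knockdown only (8.22). LAMB1 lies on chromosome 7. Targets of p53 had DNp63 in both tumours in 17 of 18 cases (percentile 100), among them GADD45A, MDM2 (101.3 and 95), CDKN1A (74.3 and 79.0) and BBC3 (78.9 and 74.1). Immediate early and AP-1 genes had it in both in 14 of 17 (percentile 100 in the control), such as ATF3 (65.7 and 49.7), FOSL1 (28.1 and 36.8), FOSL2 (34.3 and 30.6) and EGR2 (32.7 and 31.8). JUN (9.58) and JUND (5.24) had it in the control only and FOSB (5.25) in the knockdown only.

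Signalling lists were bound above the random mean less markedly. TGF-beta and BMP genes had DNp63 in both tumours in 13 of 18 cases (percentile 98.7 in the control), such as BMP7 (45.4 and 56.1), LTBP1 (45.0 and 46.6) and SMAD7 (38.0 and 34.3). TGFB3 had it in the knockdown only (8.26). NOTCH genes had it in both in 11 of 16 and in 1 tumour alone in none (percentile 97.495 in the control), with MAML2 (77.7 and 61.3), LFNG on chromosome 7 (47.0 and 57.5), JAG2 (39.3 and 46.4) and HES1 (20.2 and 23.002). WNT genes had it in both in 14 of 22 (percentile 87.6 in the control). With 16 of 22 in the knockdown their percentile there was 97.9. Strong sites were at LEF1 (95.3 and 94.7), WNT3A (67.2 and 72.2), WNT4 (46.8 and 46.0) and TCF7L2 (38.3 and 36.6). FZD1 (5.78, chromosome 7) and WNT7B (8.97) had it in the knockdown only. The position of the WNT7B peak overlapped a Pol2 peak of the control list (10.4). Hedgehog genes had it in both in 5 of 10 (percentile 67.4), with GLI3 on chromosome 7 (63.7 and 73.6), SUFU (40.0 and 46.8), GLI2 (9.17 and 14.5) and GLI1 (13.8 and 9.59), while SMO had it in the control only (6.50). Genes of mesenchymal transition and invasion were bound in both in 7 of 18 (percentile 86.6), including MMP14 (59.0 and 73.0) and PLAU (20.5 and 28.9). FN1 (7.37), S100A4 (6.44) and SNAI2 (7.37) had DNp63 in the control only, and ZEB2 (14.9) and PLAUR (5) in the knockdown only. The peaks of FN1 and SNAI2 lay within strong control Pol2 peaks (42.7 and 67.0).

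The highest control-only percentiles were those of hypoxia and glycolysis and of antigen presentation. Of 18 hypoxia and glycolysis genes, 8 had DNp63 in both tumours, such as SLC2A1, the glucose transporter GLUT1 (58.6 and 56.3), and PFKFB3 (21.4 and 24.8). There were 4 in the control only, namely PGK1 (7.15), ALDOA (6.50), LDHA (6.33) and KDM3A (4.67), against a random mean of 0.876 (percentile 99.5), and 1 in the knockdown only, PDK1 (9.70). All 4 control-only peaks lay below the median of control-only peaks (7.26). Those of PGK1 and ALDOA lay within strong control Pol2 peaks (65.2 and 77.5). The random lists were matched on gene length and not on Pol2, so this percentile does not set such signal apart. Of 14 antigen presentation genes, 5 had DNp63 in both and 3 in the control only (percentile 98.7), namely CD274, which encodes PD-L1 (15.1), TAP2 (8) and PSMB8 (5). The peak counted for TAP2 lies inside HLA-DOB, a gene outside this list. Across the 22 lists, 2 were among the highest 2.5% of random counts for control-only genes and none for knockdown-only genes. Luminal genes had DNp63 in both in 9 of 20, such as CLDN4 on chromosome 7 (31.8 and 44.3) and CDH1 (30.6 and 30.0). KRT18 (5.70), KRT19 (5.80) and XBP1 (5.67) had it in the control only. The peaks of KRT18 and XBP1 also lay within strong control Pol2 peaks (37.8 and 63.3). KRT19 and KRT15 shared their peak. Myoepithelial contractile genes had it in both in 6 of 11, such as ACTA2 (66.0 and 69.2), with MME in the control only (8.11). Cornified envelope and differentiation genes had it in both in 9 of 21, with ZNF750 (73.7 and 74.9) and GRHL3 (39.4 and 42.8), and SPRR2A in the control only (12.9). Cell cycle genes had it in both in 8 of 26, including AURKA (55.7 and 60.9) and PCNA (28.6 and 35.0), chemokines and cytokines in 9 of 24, including CSF1 (40.7 and 48.7), and interferon response genes in 7 of 23, including OAS1 and OAS3 at 1 common peak (29.1 and 34.5). IL6 on chromosome 7 had DNp63 in the knockdown only (12.0), and CXCL2 in the control only (7.15), within a control Pol2 peak (29.2). In the interferon list, IFIT3 had it in the knockdown only (8.09) and ISG20 in the control only (6.45). MCM6 (7.46) had DNp63 in the control only, within a strong control Pol2 peak (41.3), and CCND2 (6.60) and CDK2 (6.11) in the knockdown only. Housekeeping genes had DNp63 in both in 7 of 18 (percentile 90.8), with SDHA and YWHAZ in the control only. The lists of other cells and tissues stayed near or below their random means, with 3 of 10 fibroblast markers, 2 of 12 immune markers, 5 of 9 endothelial markers and 7 of 25 genes of unrelated tissues bound in both.

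**Figure D3:**
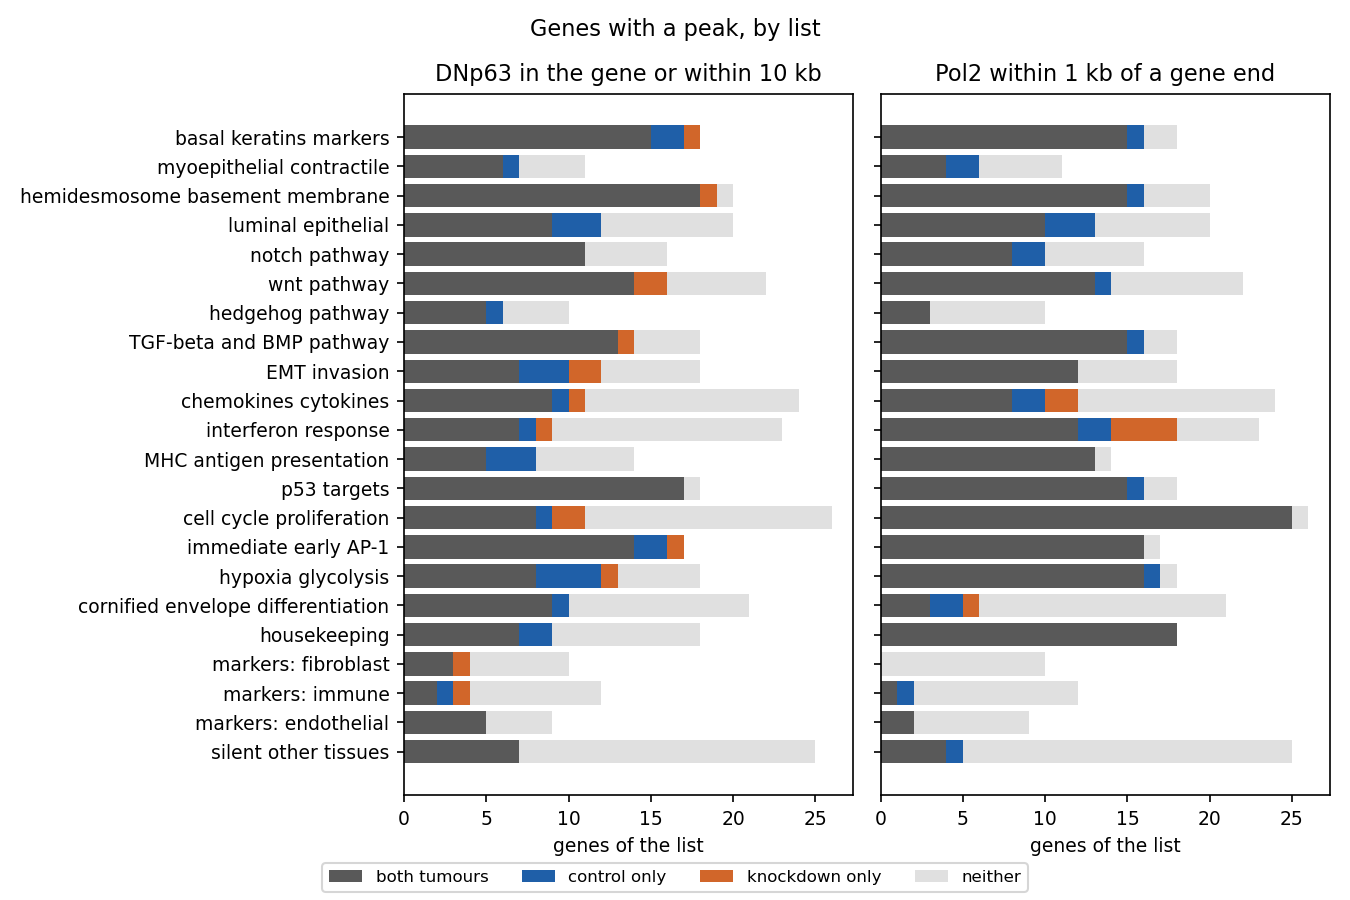
Number of genes of each list fixed beforehand (horizontal axis) with a DNp63 peak in the gene or within 10 kb (left) and a Pol2 peak within 1 kb of a gene end (right), in both tumours, in the control only, in the knockdown only or in neither; each tumour is 1 library per antibody. The p53 targets had DNp63 in both tumours in 17 of 18 cases, and the interferon list had the most knockdown-only Pol2 genes, 4 of 23.

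The next comparison asks where DNp63 sat and whether Pol2 sat with it. DNp63 was mostly away from gene ends. Of the control peaks 12.0% (11.6 to 12.5) and of the knockdown peaks 13.6% (13.1 to 14.0) had their midpoint within 1 kb of a protein-coding gene's end, 45.8% and 46.3% lay elsewhere inside such genes, and 42.2% and 40.1% lay between them. The knockdown-only peaks were at gene ends in 23.3% (22.1 to 24.6), the control-only peaks in 15.3% (14.4 to 16.3), and the shared peaks in 11.01% (control) and 11.2% (knockdown). DNp63 peaks overlapped a Pol2 peak of the same tumour in 21.2% (20.7 to 21.7) of the control and 19.9% (19.4 to 20.5) of the knockdown list, against means of 1.42% and 1.15% when the peaks were placed at random 100 times. At gene ends the overlap was 82.6% (control) and 78.7% (knockdown), and elsewhere 12.8% and 10.7%. The knockdown-only DNp63 peaks overlapped Pol2 in 29.4% (28.1 to 30.8), and the control-only peaks in 23.9% (22.75 to 25.002). Shared peaks of the same fold enrichment overlapped it in 25.7% (knockdown) and 28.7% (control). With the stronger 50% of every list, 10.9% of the control and 9.46% of the knockdown DNp63 peaks overlapped Pol2, and 7.74% and 8.50% lay at gene ends. Within 5 kb of a gene end the shares were 23.9% and 26.2%.

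For Pol2 the question is which genes carried the polymerase in either tumour. The control list was the longer and held more peaks that the other tumour lacked. Of its peaks 20788 overlapped a knockdown peak (67.2%, 66.7 to 67.8), and 22626 knockdown peaks overlapped a control peak (83.1%, 82.6 to 83.5). Every peak in the highest 20% of both lists was shared. The 10129 control-only peaks had a median fold enrichment of 6.29 against 13.3 for shared peaks, and they were inside genes away from the ends in 55.8% (54.8 to 56.8), against 33.6% (33.0 to 34.3) of the shared peaks. The 4616 knockdown-only peaks had a median of 5.75 against 9.80, with 65.1% (63.7 to 66.4) inside genes. Pol2 lay within 1 kb of a gene end at 11082 genes in both tumours, at 673 in the control only and at 115 in the knockdown only. Among Pol2 peaks matched between tumours the median ratio of knockdown to control pileup was 0.795 (1.00 for DNp63), so these counts stand beside a lower Pol2 pileup at matched peaks of the knockdown library. The strongest shared peaks were in PRDX1, a peroxiredoxin (116.2 control, 98.9 knockdown), and at the ends of NUFIP2 (105.7 and 87.5), SFPQ (104.8 and 78.9), EEF1AKMT1 (103.7 and 85.0) and NPRL3 (102.9 and 86.9). A peak at H2BC5 (104.0 and 93.6) is uncertain, since histone genes have near-identical copies.

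Only Pol2 peaks at a protein-coding gene's end were named. The control-only ones with the highest fold enrichment were at GPX8 (23.5, chromosome 5, 55159994 to 55160484), ZNF341 (20.2), GNE, an enzyme of sialic acid synthesis (19.7), GABRP, a GABA receptor subunit found in basal-like breast cancer (18.6), DNMBP (18.2), ARNT2 (18.1), ZNF175 (18.1) and MYO5B (17.97). In 7 of these 8 genes, all but GNE, the knockdown list had no Pol2 at either end. The knockdown-only ones were led by CYCS, which encodes cytochrome c (12.8, chromosome 7, 25118073 to 25119177), CASP9, the initiator caspase (12.3), GET4 (12.1), LOC124904951 (12.0), CHIC2 (11.6), TBC1D4 (11.5), CBX3 (11.2) and IRS2 (11.1). In 7 of these 8 genes, all but LOC124904951, the control list had another Pol2 peak at an end, so the site and not the gene was found in 1 tumour. CYCS, GET4 and CBX3 are on chromosome 7. The IRS2 site had a control summit within 500 bp.

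Proliferation and housekeeping genes carried Pol2 in both tumours. All 18 housekeeping genes did, such as TUBB (79.5 and 57.5), TUBA1B (75.4 and 56.9), RPS18 (73.9 and 61.4) and EEF2 (72.8 and 67.3). Cell cycle genes did in 25 of 26 cases, such as CCNA2 (45.3 and 27.2), MCM6 (41.3 and 22.1), CCNB2 (39.4 and 31.9) and CDK2 (38.3 and 26.3). Immediate early and AP-1 genes did in 16 of 17, with FOS (86.3 and 70.3), IER3 (79.3 and 64.0), IER2 (76.2 and 54.5) and KLF6 (73.8 and 40.0). Hypoxia and glycolysis genes did in 16 of 18, with ALDOA (77.5 and 53.4), SLC2A1 (75.6 and 48.9), ANKRD37 (65.4 and 46.6) and PGK1 (65.2 and 36.8), and PFKFB4 in the control only (7.31). Antigen presentation genes did in 13 of 14, with HLA-E (71.0 and 50.6), TAPBP (55.6 and 42.2), B2M (53.7 and 46.0) and HLA-C (50.8 and 32.2). HLA genes share sequence with one another and are uncertain. Targets of p53 did in 15 of 18, such as FDXR (67.0 and 44.3) and TIGAR (56.7 and 36.5), with AEN in the control only (6.39). TGF-beta and BMP genes did in 15 of 18, such as ID1 (77.5 and 61.1), ID2 (75.3 and 44.0) and SMAD4 (51.5 and 37.8), with BMP2 in the control only (7.45). In the control these 7 lists lay at percentiles from 99.1 to 100.

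The epithelial and signalling lists held from 0 to 3 genes with Pol2 in the control only, and over all genes there were 673 such genes against 115 with Pol2 in the knockdown only. Basal markers had Pol2 in both tumours in 15 of 18 cases (percentile 99.8 in the control), such as CDH3 (49.3 and 45.9), SFN (44.0 and 32.6) and NGFR (35.9 and 32.5), with KRT16 in the control only (10.3; control-only percentile 71.8). Hemidesmosome genes had it in both in 15 of 20, such as ITGB1 (54.0 and 38.3), LAMA5 (45.0 and 27.8) and ITGB4 (39.8 and 38.6), with COL17A1 in the control only (4.80; control-only percentile 61.9). Luminal genes had it in both in 10 of 20, such as XBP1 (63.3 and 47.5) and CDH1 (46.3 and 39.3). EHF, an epithelial ETS factor (14.8), FOXA1, a luminal pioneer factor (9.61), and PRLR, the prolactin receptor (6.58), had it in the control only, against a random mean of 0.672 (percentile 98.3). NOTCH genes had it in both in 8 of 16, led by JAG1 (70.9 and 46.9), with NOTCH2 (11.1) and JAG2 (4.14) in the control only (percentile 94.6). Myoepithelial genes had it in both in 4 of 11, led by TPM1 (43.0 and 29.4), with MYH11 (8.23) and MYL9 (6.62) in the control only (percentile 96.3). WNT genes had it in both in 13 of 22, led by CTNNB1, which encodes beta-catenin (85.3 and 71.7), with WNT7B in the control only (10.4). Mesenchymal transition genes had it in both in 12 of 18 and in 1 tumour alone in none, led by SNAI2 (67.0 and 35.0) and FN1 (42.7 and 26.3). Hedgehog genes had it in both in 3 of 10 (percentile 2.62), led by SUFU (39.6 and 28.4). Cornified envelope genes had it in both in 3 of 21 (percentile 0.370), namely KRT10 (39.1 and 16.9), GRHL1 (34.0 and 22.95) and CNFN (23 and 16.2). ZNF750 (9) and KLK5 (4.89) had it in the control only and S100A9 in the knockdown only (6.20).

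Interferon response genes stood out among knockdown-only Pol2 genes. Of 23 members 12 had Pol2 in both tumours, such as IRF9 (28.5 and 21.0). In the knockdown only it was found at OAS2 (9.96), IFIT1 (9.24), ISG15 (7) and OAS1 (5.98), which encode antiviral effectors. These 4 stood against a random mean of 0.141 (percentile 100). None of their peaks overlapped a control peak, which also held for 108 of all 115 knockdown-only Pol2 genes. IFIH1 (7.56) and IFIT3 (6.09) had Pol2 in the control only (percentile 91.3). Chemokines and cytokines had Pol2 in both in 8 of 24, such as CXCL2 (29.2 and 19.8) and CXCL1 (12.6 and 24.3), in the control only at CCL28 (5.67) and IL1A (5.75), and in the knockdown only at IL6 (7.67, chromosome 7) and CSF1 (4.60). That last count of 2 had percentile 99.5, against a random mean of 0.147. These 6 knockdown-only peaks had a fold enrichment below 10, and the list's median was 8.25. Of the 22 lists, 2 were among the highest 2.5% of random counts for knockdown-only and 1 for control-only Pol2 genes. Markers of other cells were mostly without Pol2, which was found at 0 of 10 fibroblast markers in either tumour. In both tumours it was found at 1 of 12 immune markers (CD8A, 16.6 and 11.4), 2 of 9 endothelial markers (PECAM1 and ERG) and 4 of 25 genes of unrelated tissues. CD14 (4.21) and GRIN1 (5.86) had it in the control only.

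The last comparison joins both antibodies and asks whether genes with DNp63 in the control only also lacked Pol2 in the knockdown list. Their share was close to that of genes with DNp63 in both tumours, and a comparison with genes of like Pol2 enrichment set it higher. Of 671 genes with DNp63 in the control only and Pol2 in the control, 36 lacked Pol2 in the knockdown list (5.37%, 3.79 to 7.35). This share was 5.94% (5.35 to 6.58) of 5773 genes with DNp63 in both, 5.87% (5.20 to 6.59) of 4517 with DNp63 in neither and 3.65% (2.46 to 5.20) of 794 with DNp63 in the knockdown only. Among random gene sets of like length these shares had percentiles of 38.7 (control only), 26.8 (both), 97.9 (neither) and 0.710 (knockdown only). When genes were matched on their Pol2 fold enrichment in the control the same share had percentile 97.4, with a random mean of 4.09%. The other classes then had percentiles of 89.9 (DNp63 in both, random mean 5.71%), 6.43 (knockdown only, 4.58%) and 8.85 (neither, 6.19%). With the stronger 50% of all lists the shares were 11.1% for genes with DNp63 in the control only and 8.98% for those with it in both. The 36 genes included RNF180, NEGR1, DNMBP, ZNF175, HLA-DOB, NES, KRT23 and EMP3. Both antibodies were found in the knockdown only at 13 of 778 genes with DNp63 in the knockdown only and Pol2 in the knockdown (1.67%, 0.893 to 2.84), while Pol2 was knockdown only at 0.876% (0.647 to 1.16) of genes with DNp63 in both and 1.14% (0.844 to 1.503) with DNp63 in neither. At 29 genes DNp63 was in the knockdown only and Pol2 in the control only. The 13 genes included IL6, C7orf33, MAPK12, PTPRZ1 and BMF, a pro-apoptotic BH3-only gene. IL6, C7orf33 and PTPRZ1 are on chromosome 7. These examples were chosen after their values were seen.

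Chromosome 7 differed from all other chromosomes in both antibodies. It held 1381 DNp63 peaks in the knockdown against 1002 in the control (ratio 1.38, 95% interval 1.27 to 1.497), while all other chromosomes together had a ratio of 0.937 (0.919 to 0.955). For Pol2 the counts were 1501 against 1244 (1.21, 1.12 to 1.30), with 0.867 (0.853 to 0.882) elsewhere. Of its knockdown DNp63 peaks 36.5% were knockdown only, against 18.5% on the other chromosomes, and of its knockdown Pol2 peaks 32.8%, against 16.0%. The lowest ratio was that of chromosome 2 for both antibodies, 0.837 (0.787 to 0.889) for DNp63 and 0.759 (0.712 to 0.809) for Pol2. Without chromosome 7 the genes with DNp63 in the control only numbered 957 and in the knockdown only 961.

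**Figure D4:**
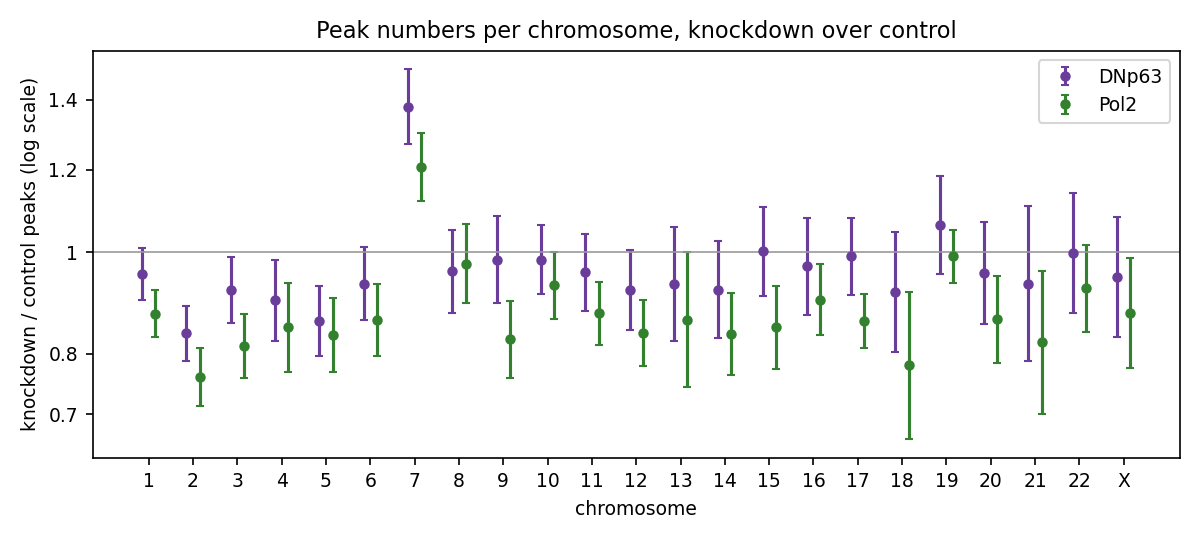
Number of knockdown peaks over number of control peaks on each chromosome, on a log scale, for DNp63 (purple) and Pol2 (green); points are ratios of 2 counts from 1 library each and bars 95% intervals that cover counting error only. Chromosome 7 stands at 1.38 and 1.21, and chromosome 2 at 0.837 and 0.759.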

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

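The tests of the runs below were set before their results were seen, and the runs themselves were noticed first and then counted by a fixed rule. Runs of at least 10 Pol2 peaks of 1 tumour, spaced at most 50 kb apart with no peak of the other tumour between them, lay mostly inside genes, which the comparison of gene ends does not use. In the knockdown tumour ARHGAP39 held 35 such peaks (chromosome 8, 144530778 to 144633061) and VANGL1, a planar cell polarity gene, 32 (chromosome 1, 115651091 to 115696476). Runs of 14 lay in PVT1, a non-coding gene next to MYC, and in MTA1, and runs of 13 in C7orf33, in ADAMTS17 and across ALDH16A1 and FLT3LG. In the control tumour KLF7, a Kruppel-like factor, held 20 and 17 peaks (chromosome 2, 207073753 to 207161666), and GABRP 19 (chromosome 5, 170755835 to 170814979). RUNX1 held 13, 14 and 10, CDCP1 and CHD2 15 each, and FN1, which encodes fibronectin, 14. TFCP2L1, FBXO32, NAV2 and the region of ST3GAL6 and DCBLD2 held 11 each, and ITGB1 and SDC4 10 each. Most peaks of the runs were weak, with median fold enrichments per run from 3.85 (PVT1) to 8.17 (FN1). Each run's median lay below that of its list (8.48 control, 8.25 knockdown). VANGL1 and ARHGAP39 had Pol2 at a gene end in both tumours, while KLF7 and GABRP had it in the control only.

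Poisson sampling of each peak's pileup would miss 12.0% of the peaks in these runs at the ratio of background levels. That scale was fixed before, in place of the unknown depth. The level followed the shortest peak length, so its ratio holds no known read depth. At the pileup scale of matched peaks, an alternative chosen after seeing the data, sampling would miss 17.7% (26.9% in the control tumour's runs). For all runs together, as the bound was set beforehand, both shares lie under the 20% for excluding sampling noise. They argue against noise at the calling limit for the runs as a set. Only the control tumour's runs at the later scale passed 20%, short of the 50% that noise would need. There 54.1 of 201 peaks would be missed, while all were absent from the knockdown list, the rule that picked them. Noise is left open for the runs of both tumours. Of 23 DNp63 peaks of the same tumour within the runs, 21.7% (7.46 to 43.7) were absent from the other tumour's list, against 21.9% in the whole lists. This leaves gain or loss of the DNA segment open, since 10 of the 22 runs held no DNp63 peak shared by both tumours, 7 of them none of the same tumour, and a gained segment need not show as absence. A difference in elongating polymerase between these tumours remains open and was not tested, since each antibody has 1 library per condition. It could come through the knockdown, through the doxycycline diet itself or through drift of the cells.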

How the results depend on the processing

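No paired analysis was possible because each group holds 1 library and no result comes from a test. The settings without chromosome 7 and with changed genes limited to those without a shared peak were chosen after seeing the data. Of the alternative values for the comparisons, 32 stayed within the interval of the value in the report (for gene counts, within 1.5 times) and 40 moved. Values are given for the control and then the knockdown tumour. With overlap of 50% of the shorter peak, 74.8% and 79.3% of DNp63 and 64.8% and 80.3% of Pol2 peaks were shared, and 20.1% and 19.0% of DNp63 peaks overlapped Pol2. With summits within 500 bp, 79.4% of knockdown DNp63 and 66.0% and 75.45% of Pol2 peaks were shared. Among the stronger 50% of every list, 81.7% and 85.9% of DNp63 and 78.8% and 94.0% of Pol2 peaks were shared, 10.9% and 9.46% of DNp63 peaks overlapped Pol2, 7.74% and 8.50% lay at gene ends, 5235 genes had DNp63 in both tumours, 605 in the control only and 652 in the knockdown only, and of genes with Pol2 in the control 11.1% lacked it in the knockdown where DNp63 was in the control only and 8.98% where it was in both. Of the strongest 25% of a list, 99.8% and 99.9% of DNp63 and 99.99% and 100% of Pol2 peaks were found in the full other list. With lists of equal length, 77.8% and 78.95% of DNp63 and 72.4% and 79.9% of Pol2 peaks were shared. Outside Pol2 peaks, 78.1% of knockdown DNp63 peaks were shared. Within 5 kb of a gene end, 4301 genes had DNp63 in both, 23.9% and 26.2% of DNp63 peaks lay at ends, and of genes with Pol2 in the control 3.73% lacked it in the knockdown where DNp63 was in the control only and 4.08% where it was in both. Without chromosome 7, 75.3% and 81.5% of DNp63 and 66.7% and 84.0% of Pol2 peaks were shared. The cause of these moves was not tested beyond what each setting removes. The knockdown list had the higher shared share in every setting for both antibodies. This follows in part from its shorter length: with summits within 500 bp, 17658 control and 17651 knockdown DNp63 peaks were shared. With lists of equal length the shares can differ only where several peaks of 1 list overlap 1 peak of the other. More genes held Pol2 in the control only than in the knockdown only under every gene rule tried, from 600 against 151 with lists of equal length to 820 against 84 with the stronger 50%. DNp63 genes in the knockdown only outnumbered those in the control only in every setting run, from 957 against 961 without chromosome 7 to 926 against 1047 within 5 kb of a gene end. The share of genes with control Pol2 that lacked it in the knockdown was lower where DNp63 was in the control only than where it was in both under all settings run but the stronger 50%, where the order turned. The named peaks of 1 tumour kept that status in 63 of 64 checks, all but IRS2 under summits within 500 bp. The planned response element search and the setting with any transcript's 5' end were not run. Depth in reads is unknown, and peaks near the calling limit were the least shared.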

Other observations

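Values of 3 further loci follow, picked after they were seen. KRT14, the keratin of basal cells, had 6 Pol2 peaks at its ends in the control list (highest 28.5) and 1 in the knockdown list (8.20). KRT5, its partner keratin, had both antibodies in both tumours (Pol2 29.6 control and 18.8 knockdown, DNp63 31.0 and 23.3). MYC had 3 Pol2 peaks at its ends in both tumours (highest 27.2 and 32.2) and DNp63 in both (9.17 and 6.83).

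For chromosome 7 all tests were chosen after the excess was seen. Of its peaks matched 1:1 between tumours, 82.1% (DNp63) and 79.3% (Pol2) ranked higher by pileup in the knockdown list, against 47.8% and 48.6% on all others together, where chromosome 2 had 34.2% and 38.4%. A few loci would not account for the excess, since 100% of the 16 windows of 10 Mb lay above the ratio of the other chromosomes. The caller's local background does not bear on this, since its knockdown to control ratio there was 1.00 times that elsewhere and it correlated between tumours at 0.986 (DNp63) and 0.994 (Pol2), as 1 common input would give. More copies of chromosome 7 in the knockdown tumour's cells may lie behind the excess of both antibodies, but a general activation of the chromosome was not excluded and no DNA copy data were at hand.

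Weak DNp63 peaks found in 1 tumour were tested against sampling noise with bounds set before the result was seen: at the pileup scale of matched peaks (median ratio 1.00), chosen after seeing the data, control-only peaks were 5.76 times and knockdown-only peaks 5.19 times as many as Poisson sampling would miss (4.74 and 6.45 times at the ratio of background levels, fixed before). The ratio of background levels holds no known read depth. Other scales brought either number under 1, but at each scale tried at least 1 of them was 5.76 or more. Pileups of peaks picked for passing a limit are biased upwards, but the excess held far from it: at −log10 p-values from 20.8 to 26.5, 22.7% (21.1 to 24.5) of control peaks were control only and 0.136% were expected at the scale of matched peaks. Knockdown-only peaks overlapped Pol2 3.73 percentage points more often than shared peaks of the same enrichment (control-only peaks 4.88 points less often), short of the 5 points set beforehand for signal at active gene ends but with an interval reaching past them, so this stays undecided. Variation between libraries, an effect of the knockdown and an effect of the doxycycline diet itself all remain. No tumour without the hairpin is among the libraries, and 1 library per group does not separate these explanations.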
